A study of Mus musculus with 24 samples.

How the data were processed

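RNA sequencing was carried out on quadriceps muscle from mice aged 16 months. The mice had been fed, from weaning, either a Control diet or a Low BCAA diet, in which the branched-chain amino acids (leucine, isoleucine and valine) were reduced. Diet and sex gave 4 groups of 6 libraries each, 24 in all, and each library was assigned to its group from the labels. Per the labels' protocols, animals were fasted overnight before the muscle was taken and frozen, and total RNA was extracted with TRI Reagent. The labels number the samples one by one, and replicate numbers follow the order of the deposited records. They do not state in words that each library came from a different mouse, so p-values measure the spread between libraries.

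The authors deposited a single table of expected counts per gene, and its name credits RSEM, a program that divides reads shared between genes among them. The values are not scaled between libraries, and 88.4% of them, zeros included, are exactly whole numbers. The genome build is mm9 per the submitters' processing notes. The RSEM version, the aligner and the annotation release are not given in the sources used here. The gene identifiers belong to a newer annotation than that build, so no chromosome positions are printed. Gene names were looked up by identifier: 51633 of the 51912 identifiers matched a name and 279 did not. Values of genes that share reads with a near-identical copy or an overlapping transcript are uncertain, because the division of such reads is a model estimate.

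Library totals lay between 30,597,878 and 43,804,992 counts (SD 3,507,400, 24 libraries). Expression is given in CPM (counts-per-million). At this depth the spread between libraries, not counting error, limited the comparisons: the common biological coefficient of variation was 35.2%. Expected counts were rounded, genes with low counts were removed with filterByExpr by group, and 18098 genes, holding 99.93% of all counts, were tested. Libraries were scaled by TMM factors.

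Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, 1 coefficient per group, 20 residual degrees of freedom) in R 4.3.3, with tables read by the data.table package (1.17.8). The 6 contrasts were Low BCAA minus Control in males, the same in females, the difference between these diet effects (interaction), their mean, and male minus female on each diet. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given as estimate ± standard error (SE), and CPM as mean ± SD over 6 libraries.

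Gene lists, 44 in all, covered metabolic and signalling pathways, fibre types, other cell types and sex-linked genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists within a contrast. An estimated correlation and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. Of the list genes, 2 haemoglobin symbols were not found in the table. For each list the number of members passing is given after adjustment over all genes tested and adjusted over the list alone.

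The groups, contrasts, tests, gene lists, main alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the genes with the largest changes among those called (in the diet contrasts 12 in each direction, with mean log2 CPM of at least 1), or the 6 genes with the smallest p in a direction where fewer than 5 passed. For the interaction it takes the 6 smallest p-values, and for sex on the Control diet the 8 largest differences in each direction. It adds 10 genes fixed in advance for the diet contrasts and up to 3 members with the smallest p from each list called. Predicted genes without a symbol were counted but not named, and some genes that the rule takes are not reported here.

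The alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, other scaling factors, other filters, fits of only the 2 groups compared, the number in the description label as a factor, a threshold of 0.1, and the removal of each library in turn. After the data had been seen, further alternatives were added: a covariate made of the mean log2 CPM of 15 hepatocyte transcripts, the removal of the 4 libraries with over 500 CPM of albumin transcript (Alb), fits without mitochondrial, 7SL and ribosomal RNA fragment genes, and fits within a single description number. Measures of single libraries were compared by exact permutation tests over all 924 splits of 2 groups, two-sided, with adjustment over the 32 tests made.

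The pipeline was tested on simulated data of the same group sizes. Of genes given a 2-fold change, 65.7% were called in the male design and 59.7% in the female design. For a 4-fold change these shares were 89.4% and 97%, and false calls made up at most 5.63% of calls.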

Results

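Gene expression was measured in quadriceps muscle of aged mice on a Control or a Low BCAA diet, with 6 Control males, 6 Low BCAA males, 6 Control females and 6 Low BCAA females. The libraries held 30,597,878 to 39,309,821 counts in Control males and 33,884,643 to 43,804,992 in Low BCAA males. They held 32,449,779 to 41,461,832 counts in Control females and 32,991,672 to 40,897,716 in Low BCAA females. Between 23182 and 26909 genes were detected per library. Mitochondrial transcripts made up 17.7% to 35.3% of counts, and titin (Ttn), a giant protein of the sarcomere, took a further 9.73% to 18.5%.

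Transcripts of other tissues and of ribosomal RNA varied widely between libraries. Albumin (Alb), a protein of hepatocytes, ranged from 1.94 to 180 CPM in Control males and 8.91 to 2590 CPM in Low BCAA males. In females it ranged from 5.47 to 679 CPM on the Control diet and 2.60 to 319 CPM on the Low BCAA diet. The 4 libraries above 500 CPM were Low BCAA male replicates 1, 2 and 4 and Control female replicate 2. Ribosomal RNA fragments took between 0.00372% and 29.1% of counts. Their mean share was 6.77 ± 11.3% in Control and 0.0128 ± 0.00658% in Low BCAA males (SD, n = 6 each; exact permutation p = 0.0325, adjusted p = 0.254). In females it was 0.424 ± 0.917% and 4.13 ± 5.85% (exact permutation p = 0.126, adjusted p = 0.288). The labels also carry a number from 1 to 3 for each library, of unstated meaning. All Low BCAA males have number 3 and all Control females number 1, while Control males have 2 or 3 and Low BCAA females 1 or 2. No number holds both sexes on the same diet, so number and group are largely confounded. Fits within a number were possible for the male diet contrast (number 3) and the female diet contrast (number 1). Each called 0 genes in edgeR, with 1213 and 2185 genes at an unadjusted p under 0.05. The only Control males with number 3 are replicates 1 and 3, and the only Low BCAA females with number 1 are replicates 5 and 6. These counts of 0 therefore carry little weight.

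The first comparison asked how the Low BCAA diet related to muscle transcripts in males. Genes of fatty acid oxidation rose as a group in Low BCAA males: 30 of 31 members were higher, with a median log2 fold change of 0.58 (camera adjusted p = 2.75e-11; adjusted p = 0.547 with an estimated correlation). Genes of BCAA catabolism, the pathway that degrades leucine, isoleucine and valine, also rose as a group, with 24 of 25 members higher and a median of 0.32 (adjusted p = 3.19e-06; adjusted p = 0.645 with an estimated correlation). Genes of fast muscle fibres fell as a group, with 14 of 15 members lower and a median of -0.25 (adjusted p = 0.000121; adjusted p = 0.649 with an estimated correlation). No single gene passed in edgeR, where the smallest adjusted p was 0.0896, against 2749 genes at an unadjusted p under 0.05. If genes were independent and unaffected, 905 would be reached, but other splits of the diet labels gave up to 2289. DESeq2 called 483 genes and limma-voom called 0.

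Among the fatty acid oxidation genes, Cpt1a (ENSMUSG00000024900), an enzyme that acts in the entry of fatty acids into mitochondria, measured 15.2 ± 4.77 CPM in Control and 42.1 ± 28.6 CPM in Low BCAA males (SD, n = 6 each). Its log2 fold change was 1.47 ± 0.338 (SE; adjusted p = 0.0896). Of the 31 members, 9 passed when adjusted over the list alone and 0 over all genes tested. White adipocyte genes were higher in 18 of 20 members in the same males (median 1.17), without the list passing (adjusted p = 0.0563; adjusted p = 0.989 with an estimated correlation); 2 members passed adjusted over the list alone and 0 over all genes. The mean log2 CPM of 15 hepatocyte transcripts was 4.61 ± 3.19 in Low BCAA and 1.85 ± 2.61 in Control males (SD, n = 6 each; exact permutation p = 0.126). With this score as a covariate the list's median was 0.588 and Cpt1a had 0.951. Without the 4 libraries richest in albumin the list's median was 0.536 and the log2 fold change of Cpt1a was 0.372. Cpt1a measured 43.4, 60.6 and 89.3 CPM in the albumin-rich Low BCAA male replicates 1, 2 and 4. In replicates 3, 5 and 6 it measured 21.2, 15.3 and 22.9 CPM. Cpt1b, another member of the list, had a log2 fold change of 0.223 in the main fit.

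In BCAA catabolism, Bckdhb (ENSMUSG00000032263), a subunit of the dehydrogenase that commits branched-chain keto acids to breakdown, measured 9.40 ± 1.12 CPM in Control and 14.4 ± 3.24 CPM in Low BCAA males, with a log2 fold change of 0.61 ± 0.121 (adjusted p = 0.0896). Aldh6a1, which acts further down the valine branch, had 0.37 (adjusted p = 0.118). Bckdha, the partner subunit of Bckdhb, had 0.58 ± 0.21 (adjusted p = 0.182). Bcat2, the muscle aminotransferase, and Bckdk, the inhibitory kinase, had 0.05 ± 0.15 and -0.01 ± 0.118 (adjusted p = 0.919 and 0.976). Both of these signs turned under some settings. In this list 4 members passed adjusted over the list alone and 0 over all genes.

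Genes of the fasting and glucocorticoid response rose as a group in Low BCAA males, 16 of 18 members being higher (median 0.81, adjusted p = 3.32e-05; adjusted p = 0.649 with an estimated correlation). Angptl4 (ENSMUSG00000002289), an inhibitor of lipoprotein lipase, measured 11 ± 6.23 CPM in Control and 45.8 ± 26.3 CPM in Low BCAA males, with a log2 fold change of 2.05 ± 0.486, and Gadd45g and Errfi1 had 2.07 and 1.20. Immediate early genes, which respond quickly to stimuli and to tissue handling, rose as a group with 16 of 20 members higher (median 0.46, adjusted p = 0.000182; adjusted p = 0.559 with an estimated correlation), among them Zfp36 at 1.57 ± 0.346, Junb at 1.49 and Egr1 at 0.88. NRF2 targets and antioxidant genes rose as a group with 20 of 23 members higher (median 0.25, adjusted p = 0.000284; adjusted p = 0.323 with an estimated correlation). Catalase (Cat), which breaks down hydrogen peroxide, measured 90.7 ± 23.8 against 211 ± 114 CPM, and Prdx6 and Gclm had log2 fold changes of 0.37 and 0.73. Adjusted over the list alone, 3, 4 and 7 members passed in these lists, and 0 over all genes.

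Of the fast fibre genes, the myosin light chain Mylpf measured 2470 ± 479 CPM in Control and 1710 ± 309 CPM in Low BCAA males (log2 fold change -0.53 ± 0.159, adjusted p = 0.127). Tnni2 and Casq1 had -0.29 and -0.39, and 1 member passed adjusted over the list alone and 0 over all genes. Circadian clock genes fell as a group, 13 of 19 being lower (median -0.29, adjusted p = 0.0312; adjusted p = 0.308 with an estimated correlation). Their members Dbp, Bhlhe40 and Nr1d2 had log2 fold changes of -2.21 ± 0.738, -1.25 and -0.47. Of this list 6 passed adjusted over the list alone and 0 over all genes, and its adjusted p was 0.0527 without Low BCAA male replicate 3. Genes of glycolysis and glycogen fell with 21 of 28 members lower (median -0.16, adjusted p = 0.00468; adjusted p = 0.649 with an estimated correlation), including Gapdh at -0.36, Pgam2 at -0.49 and Ldha at -0.39. Genes of denervation and the neuromuscular junction fell with 13 of 19 lower (median -0.31, adjusted p = 0.0374; adjusted p = 0.649 with an estimated correlation), with Rapsn, Musk and Dok7, which cluster acetylcholine receptors at the synapse, at -0.52, -0.61 and -0.54. Genes of satellite cells, the muscle stem cells, fell with 10 of 12 lower (median -0.23, adjusted p = 0.0437; adjusted p = 0.323 with an estimated correlation), with Myod1 at -1.40 ± 0.494, Itga7 at -0.24 and Myh8 at -0.36 (0.0305 with the description number as a factor). In these last 3 lists 0 members passed adjusted over the list alone and 0 over all genes. With the hepatocyte covariate their adjusted p was 0.0944, 0.106 and 0.152, and without the 4 libraries richest in albumin 0.209, 0.942 and 0.806, so these 3 calls ended.

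Beside the genes named above, the smallest p-values among higher genes in Low BCAA males included that of Ehhadh (ENSMUSG00000022853), the bifunctional enzyme of peroxisomal β-oxidation. Ehhadh had 2.71 ± 0.496 (8.09 ± 1.36 CPM in Control and 53.1 ± 48.7 CPM in Low BCAA males). The others were Clta, a clathrin light chain, at 0.35 ± 0.068, Adck2 at 0.52, and Cth, which makes cysteine from cystathionine, at 2.60 ± 0.548. Those among lower genes belonged to Atp11a at -0.50 ± 0.102, Stxbp4 at -0.98 ± 0.202, B3galnt2 at -0.74, Dtna, a member of the dystrophin complex, at -0.60, Mtf1 at -0.39 and Fut10 at -0.57. None of these genes passed in edgeR, each with an adjusted p of 0.0896. Of the genes fixed in advance, the ubiquitin ligases of muscle atrophy Trim63 and Fbxo32 had log2 fold changes of 1.57 ± 0.757 (261 ± 164 against 775 ± 306 CPM; adjusted p = 0.327) and 0.92 ± 0.49 (adjusted p = 0.379). The cell cycle inhibitor Cdkn1a had 1.40 ± 0.646 (adjusted p = 0.302), asparagine synthetase (Asns) 1.03 ± 0.529 (adjusted p = 0.356; -0.23 without the 4 libraries richest in albumin), and Ppargc1a, a regulator of mitochondrial biogenesis, -0.50 ± 0.186 (adjusted p = 0.195). Fgf21 and Cdkn2a held 161 and 11 counts over all libraries and were not tested. Leaving out 1 library moved the count of 0 called genes to 131 without Low BCAA male replicate 3, 125 without replicate 5, 46 without replicate 6 and 1 without Low BCAA female replicate 1. DESeq2 called 43 genes with the hepatocyte covariate, of which 40 were among its 483, and 6 without the 4 libraries richest in albumin, of which 4 were among them.

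**Figure D1:**
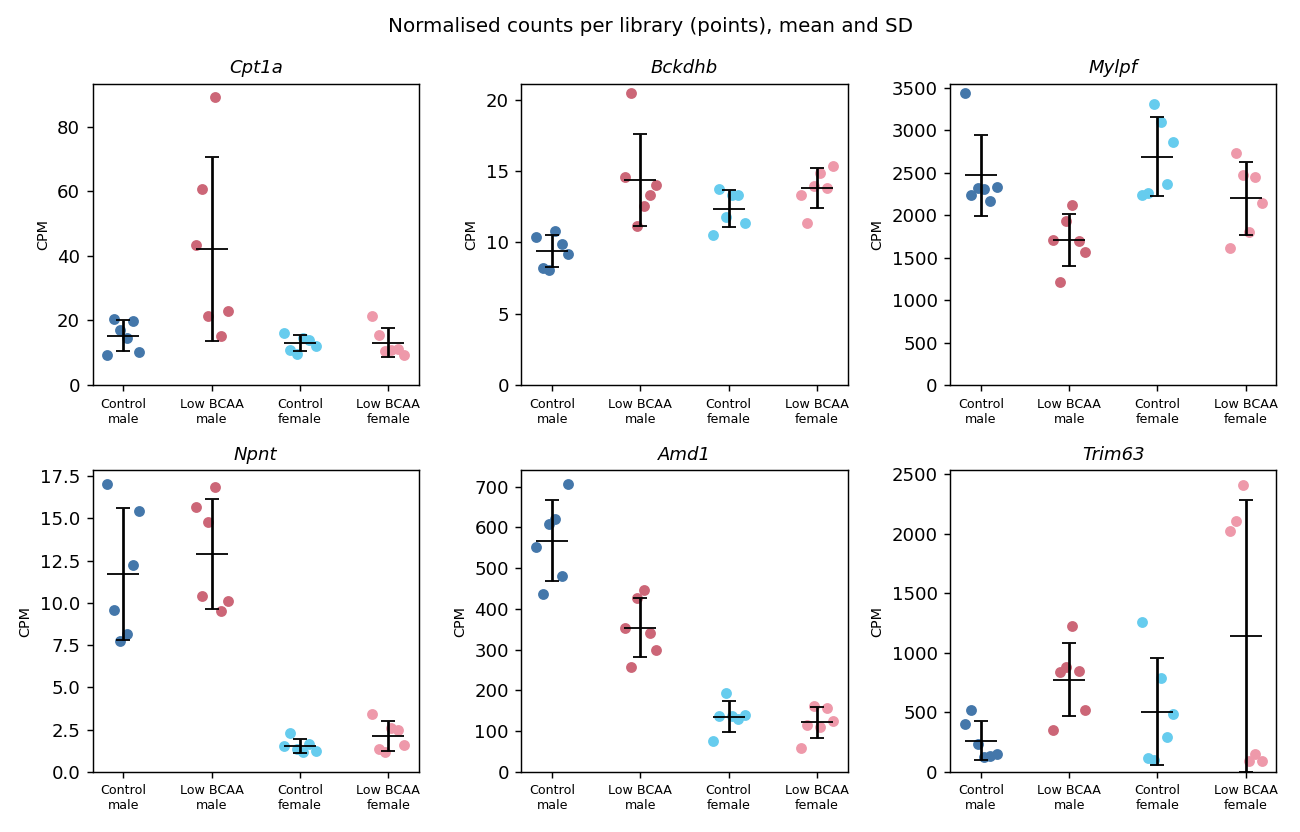
Expression of 6 genes in CPM (vertical axes) in each library of the 4 groups (horizontal axes); points are libraries, and bars show the mean and SD of 6 libraries. Npnt and Amd1 separate the sexes, with Amd1 at 567 and 354 CPM in Control and Low BCAA males and at 135 and 121 CPM in the females.

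The second comparison asked the same question in females. Interferon response genes, which act against viruses, rose as a group in Low BCAA females: 24 of 25 members were higher, with a median log2 fold change of 0.40 (camera adjusted p = 9.13e-09; adjusted p = 0.557 with an estimated correlation). White adipocyte genes rose with 18 of 20 members higher and a median of 1.29 (adjusted p = 4.24e-06; adjusted p = 0.722 with an estimated correlation). Genes of oxidative phosphorylation fell with 66 of 78 members lower and a median of -0.15 (adjusted p = 1.08e-06; adjusted p = 0.722 with an estimated correlation). No single gene passed in edgeR, where the smallest adjusted p was 0.577, against 1522 genes at an unadjusted p under 0.05; DESeq2 called 1 gene and limma-voom 0.

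Of the interferon response genes, Oas2, Oas1a and Oasl2, sensors of double-stranded RNA and their relatives, had log2 fold changes of 0.61 ± 0.217, 0.85 ± 0.307 and 0.47 ± 0.179, with Oas2 at 1.92 ± 0.367 CPM in Control and 2.93 ± 0.662 CPM in Low BCAA females (SD, n = 6 each). Macrophage genes rose with 18 of 20 members higher (median 0.31, adjusted p = 6.55e-05; adjusted p = 0.722 with an estimated correlation), with Lyz1 at 0.75, the growth factor receptor Csf1r at 0.46 and the complement gene C1qc at 0.63. Genes of fibroblasts and the extracellular matrix rose with 20 of 25 higher (median 0.27, adjusted p = 0.00496; adjusted p = 0.722 with an estimated correlation), with Sparc at 0.60, the collagen gene Col5a1 at 0.58 and Loxl1 at 0.58. All 14 tested genes of Schwann cells and nerve were higher (median 0.54, adjusted p = 0.0115; adjusted p = 0.722 with an estimated correlation), among them the myelin genes Mbp at 0.88 ± 0.35 and Pmp22 at 0.55, and Gldn at 1.05. The matrix list had an adjusted p of 0.0508 with the hepatocyte covariate and 0.122 without Control female replicate 6, and the Schwann list 0.262 without Low BCAA female replicate 1.

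Of the white adipocyte genes, the lipases Pnpla2 and Lipe had 0.65 ± 0.263 and 1.32 ± 0.534, and the fatty acid binding protein Fabp4 measured 138 ± 108 CPM in Control and 328 ± 208 CPM in Low BCAA females. Genes of fatty acid and triglyceride synthesis rose with 19 of 20 higher (median 1.18, adjusted p = 0.00508; adjusted p = 0.722 with an estimated correlation), with Agpat2 at 2.28 ± 0.822, Scd2 at 1.40 and Dgat1 at 0.70. Without Low BCAA female replicate 6 the adjusted p was 0.373. Adiponectin (Adipoq), a transcript of fat cells, measured 22 ± 21.7 CPM in Control and 61.7 ± 47.7 CPM in Low BCAA females (exact permutation p of log2 values = 0.0584). Ucp1, the uncoupling protein of brown fat, had a median of 0.0776 CPM in Control females (0 to 5.12) and 40.3 CPM in Low BCAA females (0.0298 to 119), with a log2 fold change of 5.16 ± 1.88 (adjusted p = 0.577). The ATF4 and amino acid starvation list rose with 21 of 27 higher (median 0.11, adjusted p = 0.0482; adjusted p = 0.557 with an estimated correlation), with Asns at 1.14 ± 0.53, the translation repressor Eif4ebp1 at 0.78 (-0.20 with the description number as a factor) and the tryptophan tRNA ligase Wars at 0.20. This call ended with the hepatocyte covariate (0.0728), without the 4 libraries richest in albumin (0.0627) and without Low BCAA female replicate 3 (0.176).

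Among the groups that fell in Low BCAA females, oxidative phosphorylation included Ndufa3 at -0.31 and Atp5k at -0.40, while Cox6a1, a subunit isoform common outside muscle, had 1.47 ± 0.612. Ribosomal protein genes fell with 58 of 79 lower (median -0.09, adjusted p = 0.000104; adjusted p = 0.722 with an estimated correlation), with Rpl35 at -0.35, Rpl38 at -0.26 and Rpl35a at -0.29. Fast fibre genes fell with 15 of 15 lower (median -0.24, adjusted p = 0.000185; adjusted p = 0.722 with an estimated correlation), with Tpm1 at -0.35, Myoz1 at -0.24 and Tnnc2 at -0.26. Genes of glycolysis and glycogen fell with 24 of 28 lower (median -0.19, adjusted p = 0.000388; adjusted p = 0.557 with an estimated correlation), with Pgam2 at -0.43, Gapdh at -0.28 and Ppp1r3a at -0.31. The slow fibre list had a positive median of 0.19 and a mean of -2.56e-05. Camera, which weighs each change against its error and compares the list with the other genes, called it down (adjusted p = 0.00508, and 0.722 with an estimated correlation). Smtnl1 had -0.51, Casq2 -0.57 and Myl6b 0.31, and the adjusted p was 0.107 without Control female replicate 2. Without Low BCAA female replicate 4 Myl6b turned to -0.25, while Smtnl1 and Casq2 stayed negative and moved further from 0. In each of the 12 lists called in females, 0 members passed adjusted over the list alone and 0 over all genes.

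The genes with the smallest p-values in females were, among those higher on the Low BCAA diet, the Notch ligand Jag1 (ENSMUSG00000027276) at 0.92 ± 0.205 (11.4 ± 1.73 against 21.6 ± 10 CPM), Tmem129 at 0.47, Ctps2 at 0.89, Trim67 at 3.14, spermidine synthase (Srm) at 0.57 and Wdr4 at 0.44. Among those lower were Rcsd1 (ENSMUSG00000040723) at -0.43 ± 0.097 (95.3 ± 8.40 against 70.8 ± 7.81 CPM), Arhgef6 at -0.56, A1bg at -1.92, Rnf144b at -0.46, and the overlapping pair Atcay and Atcayos at -0.97 and -0.67, whose division of reads is uncertain. None passed in edgeR, each with an adjusted p of 0.577. The mean log2 CPM of 15 hepatocyte transcripts was 2.74 in Control and 0.459 in Low BCAA females (exact permutation p = 0.154). A contribution of liver RNA to the fall of A1bg therefore stays open. Trim63 measured 506 ± 449 CPM in Control and 1140 ± 1140 CPM in Low BCAA females (1.17 ± 0.75, adjusted p = 0.672). Fbxo32 had 0.56 (adjusted p = 0.761), Cdkn1a 1.06 (0.65), Ppargc1a -0.43 (0.577), Bckdha 0.44 ± 0.21 (0.593), Bcat2 0.27 (0.624), Bckdk -0.02 (0.969) and Asns 1.14 (0.59). With the description number as a factor Trim63, Fbxo32 and Cdkn1a turned to -2.12, -1.14 and -1.27.

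**Figure D2:**
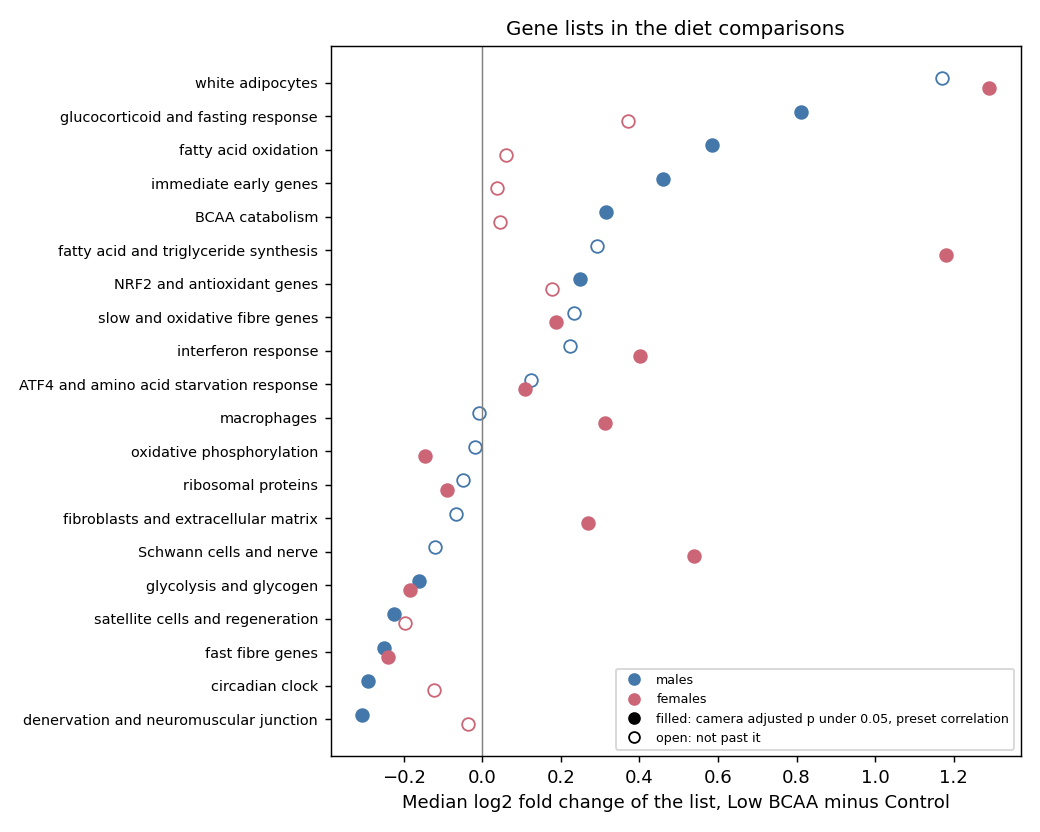
Median log2 fold change (Low BCAA minus Control, horizontal axis) of each gene list called in the male or the female diet contrast (vertical axis); filled symbols have a camera adjusted p under 0.05 with the preset correlation and open symbols do not. Fatty acid oxidation lies at 0.58 in males and 0.06 in females, and white adipocytes lie at 1.17 and 1.29.

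The third comparison asked whether the diet effect differed between the sexes. The smallest p belonged to fatty acid oxidation, where 30 of 31 members had a more positive diet effect in males than in females (median difference 0.56, camera adjusted p = 3.28e-09). Immediate early genes (median 0.48, adjusted p = 1.58e-05) and BCAA catabolism (0.23, 0.00241) also differed toward males, and macrophage genes (-0.38, 0.000321) toward females. With an estimated correlation all 11 lists called here had an adjusted p = 0.963. No single gene passed in edgeR (smallest adjusted p 0.46; 1067 genes at an unadjusted p under 0.05; DESeq2 called 6 and limma-voom 0).

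Within these lists Cpt1a had a difference of 1.44 ± 0.472, Bckdhb and Aldh6a1 had 0.45 and 0.36, and Egr1, Fos and Zfp36 had 1.58 ± 0.427, 1.74 and 1.19. Mrc1, Csf1r and Folr2 of the macrophage list had -0.54, -0.46 and -0.58. Adjusted over the list alone, 1 immediate early gene passed, 0 passed in the other lists called, and 0 over all genes. The BCAA catabolism call ended without Low BCAA male replicate 2 (adjusted p = 0.11). The 6 smallest p-values belonged to Dio1 at 6.95 ± 1.63, Ces2e at 6.09, Slc10a1 at 2.65, Aqp8 at 5.90, Slc31a2 at -0.80 and Lars2 at -10.85 ± 2.7, each with an adjusted p of 0.46. Dio1, Ces2e and Slc10a1 are abundant in liver, and their levels here were below 10 CPM on average in each group. Lars2 measured 18300 ± 32600 CPM in Control males, 45.4 ± 15 in Low BCAA males, 1770 ± 3910 in Control females and 8090 ± 10700 in Low BCAA females. Lars2 was counted here among the ribosomal RNA fragments, and its values are uncertain.

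Averaged over both sexes, 15 lists were called. Fast fibre genes fell (median -0.25, camera adjusted p = 4.83e-06), with Mylpf at -0.41 ± 0.113, Myoz1 at -0.25 and Tnnt3 at -0.29. Interferon response genes rose, 25 of 25 being higher (0.29, 4.83e-06), with Rsad2 at 0.52, Bst2 at 0.61 and Ifit1 at 0.40. White adipocyte genes rose, 19 of 20 being higher (1.16, 8.34e-05), with Pnpla2 at 0.85 ± 0.186, Lipe at 1.33 and Cidea at 3.53. Fatty acid oxidation (0.35, 6.33e-06), BCAA catabolism (0.19, 9.17e-05), glucocorticoid and fasting response (0.68, 0.00025), NRF2 and antioxidant genes (0.20, 0.000548), autophagy and lysosome (0.13, 0.0194) and the ATF4 list (0.08, 0.033) rose as groups. Glycolysis and glycogen (-0.18, 8.36e-05), oxidative phosphorylation (-0.08, 0.000436), ribosomal proteins (-0.07, 0.000876), the circadian clock (-0.20, 0.0116), satellite cells (-0.16, 0.0154) and denervation genes (-0.14, 0.039) fell as groups. With an estimated correlation none of the 15 was called, the smallest being adjusted p = 0.183 with an estimated correlation. Single libraries ended 4 of these calls: the largest adjusted p was 0.0803 for the ATF4 list and 0.0965 for autophagy without Low BCAA female replicate 3, 0.167 for denervation without Low BCAA male replicate 1 and 0.29 for ribosomal proteins without Control male replicate 1. Without the 4 libraries richest in albumin, oxidative phosphorylation had 0.991, denervation genes 0.772 and satellite cells 0.172. Adjusted over the list alone, 11 adipocyte, 8 fast fibre and 7 BCAA catabolism genes passed, and 0 over all genes.

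Examples in the groups averaged over both sexes included the autophagy genes Gabarapl1 at 1.15 ± 0.305 and Ulk1 at 0.76, the leucine sensor Sesn2 at 0.98 ± 0.247, Bckdhb at 0.39 ± 0.085 and Bckdha at 0.51. Among lower genes were Ciart at -1.03, Ankrd1 at -0.96, Tpi1 at -0.27, Rpl31 at -0.22 and Chrnb1 at -0.29, while Cox8a, of the oxidative phosphorylation list, had 1.07. No gene passed in edgeR, where the smallest adjusted p was 0.0538, against 3286 genes at an unadjusted p under 0.05; DESeq2 called 783 genes and limma-voom 0. Without the 4 libraries richest in albumin DESeq2 called 21, of which 19 were among the 783, and with the hepatocyte covariate 766, of which 684 were. With quality weights limma called 435 genes. Leaving out 1 library gave 463 called genes without Low BCAA male replicate 3, 286 without Control female replicate 1, and 164 and 146 without Low BCAA female replicates 4 and 5. It gave 2 without Control male replicate 2 or Low BCAA male replicate 6, and 1 without Low BCAA male replicate 1 or 2 or Control female replicate 2. Across all tested genes the male and female log2 fold changes had a Pearson r of -0.0455 and a Spearman rho of 0.278 (permutation p of diet labels within sex 0.78 and 0.07), and genes are not independent replicates. The sign of r turned without Low BCAA male replicate 4 (0.0145), Control female replicate 2 (0.065) or Low BCAA female replicate 4 (0.0166), and r was -0.201, -0.123 and -0.122 without Low BCAA female replicates 1 and 2 and Control female replicate 6.

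Lists that were not called in any of the 6 comparisons included several linked to amino acid supply. Averaged over both sexes, the medians were 0.01 for the mTORC1 complex and amino acid sensing (camera adjusted p = 0.55, with a mean of 0.08 against a test pointing down), 0.15 for amino acid transport (0.319), 0.08 for insulin and IGF signalling (0.527), 0.14 for atrophy and FoxO targets (0.49), -0.09 for mitochondrial biogenesis (0.319) and 0.05 for the unfolded protein response (0.234). They were -0.04 for heat shock (0.319), 0.14 for sterol synthesis (0.527), -0.03 for senescence (0.666, with a mean of 0.20), -0.32 for tendon (0.176) and 0.24 for B and plasma cells (0.29). In the atrophy list 6 members were higher and 3 lower when adjusted over the list alone, and 0 over all genes.

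The fourth comparison asked how muscle differed between the sexes on the Control diet. Amd1 (ENSMUSG00000075232), which commits S-adenosylmethionine to polyamine synthesis, measured 567 ± 98.8 CPM in males and 135 ± 37.8 CPM in females (SD, n = 6 each), a log2 difference of 2.07 ± 0.221 (adjusted p = 5.58e-06). Smox, which oxidises spermine, was higher in males at 76.6 ± 15.6 against 30.7 ± 9.67 CPM (1.32 ± 0.22, adjusted p = 0.00274). The matrix protein nephronectin (Npnt, ENSMUSG00000040998) measured 11.7 ± 3.88 CPM in males and 1.53 ± 0.419 CPM in females (2.93 ± 0.27, adjusted p = 5.7e-07), and the complement gene C7 11.9 ± 6.07 against 0.857 ± 0.403 CPM (3.78 ± 0.408, adjusted p = 6.11e-06). In all, edgeR called 75 genes, 50 higher in males and 25 higher in females, and 1406 had an unadjusted p under 0.05.

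Other genes higher in males included the phosphodiesterase Pde11a at 3.15 ± 0.326, the zinc transporter Slc30a2 at 3.05 ± 0.333, Tmem132b at 2.31 and the antisense transcript Irx3os at 3.82. Amd2, a near copy of Amd1, had 2.37 ± 0.312, and the division of reads between the copies is uncertain. Genes higher in females were A1bg at -2.32 ± 0.493 (2.10 ± 0.629 CPM in males, 10.6 ± 10.6 in females) and the phospholipase Pla2g5 at -2.27. They also included Tmem266 at -1.83, the adenylate kinase Ak4 at -1.49 ± 0.306, Fsbp at -1.45, the cadherin Fat3 at -1.43 ± 0.3, Hmgn5 at -1.34 and Cyp4f39 at -1.29 ± 0.246. These 8 had adjusted p between 0.0117 and 0.0449. The SD of A1bg in Control females was as large as its mean, and Alb ran from 5.47 to 679 CPM in these libraries. A contribution of liver RNA to the A1bg difference therefore stays open. The one-carbon and polyamine list was called higher in males (median 0.05, camera adjusted p = 0.0296; adjusted p = 0.629 with an estimated correlation). In it 4 members passed adjusted over the list alone and 3 over all genes.

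The sex-linked lists matched the labels in their group means. Ddx3y, on the Y chromosome, measured 82.6 ± 9.06 CPM in males and 0.248 ± 0.434 CPM in females. The list of 4 Y-linked genes had a median of 7.79 (adjusted p = 1.59e-42; adjusted p = 7.67e-06 with an estimated correlation). Xist, the RNA that silences an X chromosome, measured 1.24 ± 2.06 CPM in males and 315 ± 21.1 CPM in females. In Low BCAA females, Xist was at 0.0776 CPM in replicate 4. The Xist list also holds genes that escape silencing, among them Kdm6a at 19.6 ± 2.58 against 39.2 ± 6.71 CPM, Eif2s3x at -0.70, Kdm5c at -0.67 and Ddx3x at -0.60. On the Control diet this list was lower in males (adjusted p = 5.74e-14; adjusted p = 0.0132 with an estimated correlation).

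Other lists were called on the Control diet with the preset correlation alone. Ribosomal protein genes were lower in males, 70 of 79 members (median -0.14, adjusted p = 5.74e-14), as in Rpl35 at -0.50 ± 0.121, Rpl23 at -0.36 and Rps24 at -0.31. Proteasome genes (-0.14, 0.000793), translation factors (-0.09, 0.044), red blood cells (-1.17, 0.0352), immediate early genes (-0.29, 0.0269) and slow fibre genes (-0.97, 0.0394) were lower in males. Endothelium (0.26, 0.000793), extracellular matrix (0.16, 0.0113), pericytes (0.34, 0.0229) and the interferon response (0.12, 0.0269) were higher in males. These 10 lists had an adjusted p = 0.972 with an estimated correlation. Single libraries ended 8 calls, with the largest adjusted p at 0.899 for red blood cells and 0.0559 for pericytes without Control female replicate 3, 0.172 for translation factors and 0.24 for extracellular matrix without replicate 6, and 0.236 for immediate early genes and 0.0732 for the polyamine list without replicate 1. Without Control male replicate 1 it was 0.74 for slow fibre genes (0.303 without the 4 libraries richest in albumin) and 0.209 for the interferon response. With the description number as a factor edgeR called 7 genes, 5 of them among the 75, and all 75 kept their sign. The 7 include Amd1, Amd2, Npnt and Pde11a, but neither Xist nor a Y-linked gene. All Control females have number 1 and no Control male does, so this fit had little power. Its lost calls therefore do not speak against a sex difference. DESeq2 called 146 genes and limma with quality weights 159.

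The last comparison asked the same on the Low BCAA diet. Amd1 was again higher in males, at 354 ± 72.5 against 121 ± 37.7 CPM (1.55 ± 0.217, adjusted p = 0.000403), as was Smox at 53.7 ± 8.29 against 23.4 ± 8.34 CPM (1.20 ± 0.219, adjusted p = 0.00855). Ahcy, which hydrolyses S-adenosylhomocysteine, measured 67.8 ± 53.3 CPM in males and 20.7 ± 6.00 CPM in females (1.72 ± 0.37, adjusted p = 0.0304). The SD of Ahcy in males was large beside its mean, and Alb ran from 8.91 to 2590 CPM in these males. A contribution of liver RNA to the Ahcy difference therefore stays open. The one-carbon and polyamine list was higher in males (median 0.12, camera adjusted p = 5.59e-06, and 0.0164 with an estimated correlation). Its camera adjusted p was 0.000296 with the hepatocyte covariate and 0.0225 without the 4 libraries richest in albumin. In it 8 members passed adjusted over the list alone and 4 over all genes. In all, edgeR called 135 genes, 85 higher in males and 50 higher in females, and 2067 had an unadjusted p under 0.05. The count was 59 with the hepatocyte covariate and 36 without the 4 libraries richest in albumin, and DESeq2 called 498 genes and limma-voom 77. Of the genes called on the Control diet, 33 of the 50 higher in males and 11 of the 25 higher in females were called again; 0.235 and 0.0691 would be shared if the calls were independent.

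Fatty acid oxidation genes were higher in Low BCAA males than in Low BCAA females, 30 of 31 members (median 0.52, adjusted p = 8.55e-10; adjusted p = 0.509 with an estimated correlation). Cpt1a measured 42.1 ± 28.6 against 13.1 ± 4.58 CPM (1.68 ± 0.34, adjusted p = 0.0182). Of this list 2 members passed adjusted over the list alone and 1 over all genes. The mean log2 CPM of the 15 hepatocyte transcripts was 4.61 ± 3.19 in these males and 0.459 ± 2.84 in these females (SD, n = 6 each; exact permutation p = 0.0476, adjusted p = 0.254). Genes of granulocytes and mast cells were lower in males (median -1.46, adjusted p = 2.41e-05; adjusted p = 0.213 with an estimated correlation). Of these, the mast cell proteases Mcpt4 and Cma1 had -1.46 ± 0.318 and -1.73 ± 0.376 (adjusted p = 0.0309 for both), at levels of 0.87 ± 0.285 and 0.727 ± 0.28 CPM in males. Of this list 4 members passed adjusted over the list alone and 2 over all genes. Cd3e of the T and NK cell list (median -1.63, adjusted p = 0.0387; adjusted p = 0.921 with an estimated correlation) had -1.91 ± 0.452 (adjusted p = 0.0468). That list had an adjusted p of 0.379 without Low BCAA female replicate 5.

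The Y-linked list again separated the sexes (median 9.61, adjusted p = 1.97e-38; adjusted p = 1.65e-05 with an estimated correlation), as did the Xist list (-0.72, 1.06e-09; adjusted p = 0.0443 with an estimated correlation). Xist measured 302 ± 151 CPM in Low BCAA females. Macrophage (-0.51, 0.000241), Schwann cell (-0.46, 0.00732), MHC class II (-0.77, 0.00777) and ribosomal protein genes (-0.11, 1.5e-06) were lower in males, each with an adjusted p = 0.91 with an estimated correlation. Endothelial genes (0.24, 5.23e-05) and immediate early genes (0.25, 0.00538) were higher in males, with adjusted p = 0.81 and 0.813 with an estimated correlation. Oxidative phosphorylation (0.09, 0.00589) and the TCA cycle (0.16, 0.0115) were higher in males, each with an adjusted p = 0.921 with an estimated correlation. Without Low BCAA male replicate 5 these last 2 lists had 0.313 and 0.184, without Low BCAA female replicate 5 MHC class II and immediate early genes had 0.0709, and without replicate 1 Schwann cell genes had 0.242 (0.159 without the 4 libraries richest in albumin). Single libraries moved the count of 135 genes: it was 246 and 220 without Low BCAA male replicates 5 and 6 and 204 without Low BCAA female replicate 1. It was 79 and 64 without Low BCAA male replicates 2 and 4, and 79, 66 and 65 without Low BCAA female replicates 2, 5 and 6. With the description number as a factor 5 genes were called, all 5 among the 135 and 4 of them Y-linked genes, and the 135 kept their sign. Amd1, Smox, Ahcy, Cpt1a, Mcpt4, Cma1 and Cd3e were not called there. No number holds both sexes on this diet, so this fit had little power.

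The spread of the samples was examined on the 500 most variable genes. The first principal component held 56.1% of the variance and followed the hepatocyte score over the 24 libraries (Pearson r = 0.983, Spearman rho = 0.99, permutation p = 1e-05 for both). This p is the smallest that 100000 resamples can give, and r was 0.983 without the 2 farthest libraries. Within the groups r was 0.985 in Control males, 0.996 in Low BCAA males, 0.987 in Control females and 0.997 in Low BCAA females. The first component did not separate the diets beyond the spread between libraries (exact permutation p = 0.0823 in males and 0.221 in females). Over the 32 such tests of library measures the smallest adjusted p was 0.254.

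**Figure D3:**
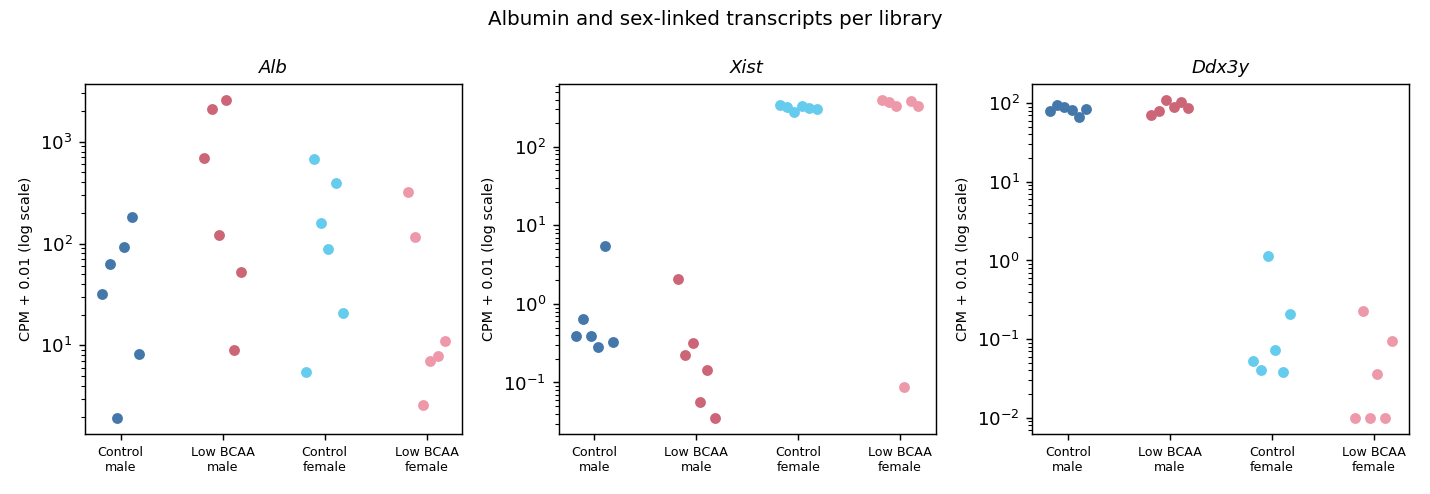
Levels of Alb, Xist and Ddx3y in CPM plus 0.01 (vertical axes, log scale) in each of the 24 libraries by group (horizontal axes); each point is 1 library. Alb runs from 1.94 to 2590 CPM, and Low BCAA female replicate 4 has Xist at 0.0776 CPM, while the other female libraries have 282 to 400 CPM.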

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

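The tests of hepatocyte transcripts, of liver RNA behind the fatty acid oxidation list, of a male library under a female label and of sex by unadjusted counts over the splits were chosen after the results they concern had been seen, while the other tests by splits of the samples and that of a single X chromosome were fixed before. The splits were drawn again after a first draw, which counted mirrored and repeated splits, had been seen. By the limit fixed on the share of splits, only the reading of the fatty acid oxidation list turned, from chance excluded to not excluded.

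Alb, the albumin transcript of hepatocytes, ran from 1.94 to 2590 CPM in these muscle libraries, and 14 other hepatocyte transcripts followed it with a median Pearson r of 0.971 over 24 libraries. Liver RNA or liver cells in some libraries may therefore be a source, while spill-over from 1 pool of liver RNA of both sexes was argued against, since female-biased liver transcripts per 1000 albumin transcripts were 0.0715 to 23.6 in 5 male and 35.2 to 98.3 in 5 female libraries with over 100 CPM of Alb, and the ratio of medians was 0.00709. Male-biased ones were 23.7 to 140 in the male and 1.67 to 28.4 in the female libraries (medians 71.1 and 2.02), where Control female replicate 3 lay above Low BCAA male replicate 4. A diet effect and other sources cannot be told apart, because the hepatocyte score was 2.755 higher on the Low BCAA diet in males and -2.282 in females, with a larger exact permutation p of 0.154 and only 6 libraries per group. Carry-over at dissection or RNA extraction stays open and was not tested, and diet was the only biological explanation tested.

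The fatty acid oxidation list was higher in Low BCAA males, and its diet effect differed between the sexes (camera adjusted p = 2.75e-11 and 3.28e-09), but neither passed with an estimated correlation (0.547 and 0.963). Liver RNA as the whole cause was argued against by the list's median of 0.588 with the hepatocyte covariate (0.438 to 0.695 over fits without 1 library, SD 0.064), although Cpt1a went from 1.47 to 0.951, so liver RNA may contribute to single members. Of 100 splits of diet within sex, 10 gave a list median as far from 0, with 0.584 for the real split and 0.786 for the highest other, so chance cannot be excluded. All 462 splits of the males gave an exact permutation p of 0.0996 for the list's median difference in mean log2 CPM, which was 0.534. A diet effect and the description number, which is 3 in all Low BCAA males, stay open.

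Low BCAA female replicate 4 had Xist at 0.0776 CPM (3 raw counts), where the other libraries of its group had 330 to 400 CPM. A male library under a female label was argued against, as its Y-linked transcripts reached 0.000567 of the lowest male library's level. Its mean log2 CPM over 4 genes that escape X inactivation was 5.56, below the 6.25 to 6.84 of the other 11 female libraries and beside the 5.60 to 5.92 of the 12 male libraries. A single X chromosome may therefore be the cause, in the animal or in the sampled tissue. In the same library Eif2s3x was at 58.9 CPM (94.9 to 116 in the others of its group) and Kdm5c at 28.9 CPM (48.9 to 64.6).

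Splits of the samples bear on the counts of genes. In males 1 of 100 splits, the real one, gave as many genes at an unadjusted p under 0.05 (2749, highest other 2289), and over both sexes also 1 (3286, highest other 2306), so chance can be excluded for these counts. In females 19 splits gave as many (1522, highest other 3470) and for the interaction 39 (1067, highest other 3204), so chance cannot be excluded there. For sex on the Control diet 1 split called as many genes (75, highest other 2), so chance is unlikely for these called genes. On the Low BCAA diet 4 did (135, highest other 427), which is below the limit fixed on the share of splits. Since 3 of these splits called more genes than the real one, chance is not firmly excluded for this count. At an unadjusted p under 0.05, 2 splits gave as many on the Control diet (1406, highest other 1628) and 21 on the Low BCAA diet (2067, highest other 3731), so chance cannot be excluded for the latter count. On the Low BCAA diet the other 3 called 225, 316 and 427 genes, the last several times the real count, which points to a structure of the samples whose source was not tested. DESeq2 calls were reached by 2 splits in males (483, highest other 484), which is below the same limit. Since 1 of these called more genes than the real split, chance is not firmly excluded in males. Over both sexes 1 split, the real one, reached the count (783, highest other 112), so chance is unlikely for it. Without the 4 libraries richest in albumin these DESeq2 counts were 6 and 21, and splits were not run there.

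The diet effect differed between males and females, by camera on the interaction, for 11 lists, each with an adjusted p = 0.963 with an estimated correlation. Fatty acid oxidation, immediate early genes (1.58e-05), glucocorticoid and fasting response (0.0149) and BCAA catabolism (0.00241) had a more positive effect in males. Red blood cells (0.0039; median 1.45), oxidative phosphorylation (0.00495; 0.12) and slow fibre genes (0.0454; 0.29) did too. Macrophages (0.000321), extracellular matrix (0.0039) and the interferon response (0.0185) had a more positive effect in females. Granulocytes and mast cells (0.0151) were called toward females with a median of -0.881 and a mean of 0.0656. Without 1 library the largest adjusted p was 0.252 for glucocorticoid genes (Control female replicate 1), 0.179 for oxidative phosphorylation (Low BCAA female replicate 5), 0.121 for interferon (Low BCAA female replicate 6), 0.52 for slow fibre genes (Control male replicate 1), 0.065 for extracellular matrix (Low BCAA male replicate 4), 0.0974 for granulocytes (Control female replicate 5) and 0.0843 for red blood cells (Control female replicate 3). Extracellular matrix and granulocytes had 0.0549 and 0.0605 with the hepatocyte covariate.

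Of 348 sets of 6 libraries searched for a sample far from the others, 24 held one, and about 1 in 20 would by chance. Control male replicate 1 had Mylpf at 3440 CPM (2170 to 2330 in the others of its group) and Tnni2 at 3440 (2680 to 2940). It also had Tmem132b at 47.7 (26.3 to 30.7) and Ak4 at 0.713 (4.38 to 6.48). Low BCAA male replicate 2 had Fut10 at 5.13 (6.9 to 7.97), Gapdh at 1560 (1980 to 2240) and Pgam2 at 198 (274 to 303). Low BCAA male replicate 3 had Gadd45g at 2.03 (16.9 to 24) and Zfp36 at 6.09 (12.4 to 18.6). Low BCAA male replicate 1 had Eif2s3y at 23.4 CPM (31.6 to 35.7). Control male replicate 2 had A1bg at 3.37 (1.7 to 2.04), replicate 4 had Ucp1 at 16.4 (0.0255 to 0.403) and replicate 5 had Xist at 5.44 (0.273 to 0.626). Control female replicate 3 had Eif2s3y at 0.475 (0 to 0.0336), Uty at 0.85 (0 to 0.0336), Pnpla2 at 40.1 (75.5 to 109) and Alas2 at 42.3 (5.46 to 10.8). Control female replicate 6 had 2.29% ribosomal RNA fragments (0.00635 to 0.194). Low BCAA female replicate 4 had 28.1% mitochondrial transcripts (17.7 to 21.4) and Casq2 at 52 CPM (3.48 to 8.2), and replicate 6 had Loxl1 at 10.1 (2.57 to 3.62).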

How the results depend on the processing

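The hepatocyte covariate and the fits without the 4 libraries richest in albumin, by edgeR or DESeq2, were chosen after the data had been seen. No paired analysis was possible because the replicate numbers follow the order of the records and pair nothing. Another pseudocount was not run, since the table holds counts. The cause of the changes listed here was not tested.

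Counts of called genes stayed at 0 in females and for the interaction in each fit without 1 library, and ranged from 0 to 131 in males, 0 to 463 over both sexes, 53 to 87 for sex on the Control diet and 64 to 246 on the Low BCAA diet. At a threshold of 0.1 they were 129 in males, 539 over both sexes, 113 and 316 for sex. DESeq2 called 483 (males), 1 (females), 6 (interaction), 783 (both sexes), 146 and 498 (sex). With the hepatocyte covariate DESeq2 called 43, 49, 7 and 766 in the diet contrasts, and without the 4 libraries 6, 20, 3 and 21. For sex on the Control diet it called 160 and 150 in these fits. Fits of only the 2 groups compared called 4 in males and 27 for sex on the Low BCAA diet. Quality weights gave 435 over both sexes, 159 and 59 for sex. Over both sexes upper-quartile factors gave 1, the mean of at least 1 CPM 93 and the hepatocyte covariate 22. For sex on the Low BCAA diet voom gave 77, the covariate 59 and the fit without the 4 libraries 36. The description number left 7 and 5 genes for sex, in fits of little power, because no number holds both sexes on the same diet.

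With an estimated correlation 0 lists were called in each diet contrast and the interaction, 2 for sex on the Control diet and 3 on the Low BCAA diet. Fry called 1 in males, 0 in females, 0 for the interaction, 5 over both sexes, 2 and 4 for sex. The interaction had 17 lists without the 4 libraries. Without 1 library the number of lists was 8 to 17 in males (17 without Control male replicate 1), 11 to 21 in females (21 without Control female replicate 4), 8 to 18 for the interaction (18 without Low BCAA female replicate 3), 13 to 20 over both sexes, 12 to 16 for sex on the Control diet and 10 to 23 on the Low BCAA diet (23 without Low BCAA male replicate 1). The r between the diet effects of the sexes lay between -0.201 and 0.065 without 1 library, being positive without Low BCAA male replicate 4 (0.0145), Control female replicate 2 (0.065) and Low BCAA female replicate 4 (0.0166). The first component held 25.6% of the variance with all genes and 57.9% without the sex-linked lists.

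Of 277 pairs of a named gene and a contrast, voom kept the sign and side of the threshold in 267, upper-quartile factors in 275, the hepatocyte covariate in 267 and the description number in 232 (31 no longer passed and 14 turned sign). DESeq2 kept 215 of 272 (57 newly passed) and the fit without the 4 libraries 259 of 275. With the description number as a factor the sign turned for Bcat2 (-0.0653) and Myh8 (0.0305) in males, Trim63 (-2.12), Fbxo32 (-1.14), Cdkn1a (-1.27) and Eif4ebp1 (-0.20) in females, and Gadd45a (-0.16) and Sesn1 (-0.0695) over both sexes. For sex it turned for Pdgfrb (-0.0469), Psmd8 (-0.27), Ier5 (-0.16), Sox10 (0.0522), Gldn (0.67) and Cd4 (0.94). Bcat2 in males was -0.00152 with upper-quartile factors and -0.00549 without the 4 libraries, which also gave Bckdk 0.17 and Asns -0.23, while the covariate gave Bckdk 0.0745. Without 1 library Bcat2 ranged from -0.046 to 0.156 in males, Bckdk from -0.0764 to 0.0726 in males and -0.0548 to 0.0198 in females, and Myl6b from -0.25 to 0.52 in females. The other ranges were -0.277 to 5.48 (S100a9, interaction) and -0.635 to 0.126 (Myl6b, interaction).

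In simulated data of this depth and group size, 25.4% of 1.5-fold changes and 65.7% of 2-fold changes were called in males, so smaller effects could not be excluded. Genes varied independently in the simulation, so these shares may not hold for the real libraries.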

Other observations

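The values of single libraries in this part were chosen after they had been seen, while the tests of gene lists were fixed before, and all are given without explanation.

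Genes of B and plasma cells had a median log2 difference of -2.72 between males and females on the Control diet, with 9 of 10 members passing adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0502). Cd79a, part of the B cell receptor, was at 6.30 CPM in Control female replicate 3 and 3.40 CPM in Low BCAA female replicate 5, against a median of 0.252 CPM over the 24 libraries. The other Control females had 0 to 0.403 CPM and the Control males 0.0522 to 0.369 CPM, so replicate 3 carried the difference in this gene. Genes of T and NK cells had a median of -1.81 on the Control diet (adjusted p = 0.0708). Ucp1 had its highest value, 139 CPM, in Low BCAA male replicate 2. Myh7, the slow myosin, reached 1520 CPM in Low BCAA female replicate 4, against a median of 2.85 CPM over all libraries, and the fast myosin Myh4 was 23500 CPM there, the lowest of the 24.

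Tendon genes were lower in 12 of 12 members in Low BCAA males (median -0.37, camera adjusted p = 0.0778). In the polyamine list, 5 members were higher and 2 lower in Low BCAA males when adjusted over the list alone, and 0 over all genes (adjusted p of the list = 0.438).

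Control female replicate 3 held Y-linked transcripts summing to 2.98 CPM and male-biased liver transcripts at 28.4 per 1000 albumin transcripts, while the male libraries' Y-linked sums were 137 to 194 CPM. Control male replicate 5 held Xist at 5.44 CPM and female-biased liver transcripts at 23.6 per 1000 albumin transcripts. The labels of these libraries share a letter and differ in their number.

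Ribosomal RNA fragments took 0.00372% to 0.0236% of counts in the 8 libraries with description number 3, 0.0125% to 29.1% in those with number 2 and 0.00635% to 15% in those with number 1. Lars2 ran from 19.8 to 66.7 CPM with number 3, 45.9 to 83700 CPM with number 2 and 29.7 to 27200 CPM with number 1.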
